A study of Caenorhabditis elegans with 2 samples.

How the data were processed

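Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans of a strain whose madf-6 gene carries a CRISPR insertion encoding EGFP, so that the protein could be recovered with an antibody against GFP. Animals were synchronised as starved first-stage larvae and collected as young adults at 63 h, and chromatin was sheared by sonication, per the labels. There was 1 group, with 2 biological replicates that the labels number separately. Neither an untagged strain nor a second stage or tissue was analysed here, so the only comparison between samples is that of the replicates, and every other comparison is between parts of the genome.

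The deposited material used here consists of 8 peak lists on the ce11 assembly, which is WBcel235 under another name, and no peak reached beyond a chromosome end of that assembly. Each replicate has its own ranked list, made before thresholding, and its own thresholded list. The other 4 lists combine the replicates: a ranked list and a conservative thresholded list, and a second ranked list with a less strict thresholded list. Peaks were called against a single control library shared by both replicates, per the text deposited beside the lists. The aligner, the peak caller and their settings are not given in the sources used here. The score of each peak is a scaled irreproducible discovery rate that the authors deposited, capped at 1000 and at least 830 in the 4 thresholded lists. The signal of each peak is the authors' own enrichment value, deposited with the peak. Its scale differs between lists, so it was used only to rank and describe peaks within a list. The position of each summit is the deposited offset from the peak start. In the ranked list behind the conservative list 4441 peaks reached that score, of which 4384 are in the conservative list. A further input file that the deposited text does not describe was used in making the thresholded lists. The 2 ranked lists that combine the replicates hold 4 unnamed columns of values per call, which were not used.

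The files give no read counts, so the depth of each sample is unknown. Intervals are 95% Wilson intervals for shares, cover counting error only and treat peaks or genes as independent, which neighbouring genes and overlapping peaks are not.

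Coordinates are 1-based. Genes were taken from the Ensembl release 115 annotation, which holds 19973 protein-coding genes on the 6 nuclear chromosomes. A gene was called bound when a summit of the conservative list lay within 500 bp of its annotated 5′ end. That end need not be the start of transcription, because many transcripts of this species are trans-spliced, and a summit between divergent genes counted for each of them. Summits were assigned to a single location in the order promoter (up to 500 bp upstream of a protein-coding gene), 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene and other intergenic sequence.

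Observed shares were set against 1000 random placements of peaks or summits within their own chromosomes. These permutation tests give a smallest p of 0.001 one-sided, used for replicate overlap, and 0.002 two-sided, used for locations. Peaks were counted as shared from an overlap of 1 bp. Gene lists were compared with the other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over all 30 lists, so that each adjusted p is adjusted over those lists alone. The lists were chosen by gene name and fixed before the data were examined, as were the other tests, the naming rule and all alternatives except those listed as later additions. By that rule the text names the madf family, the genes at the 25 peaks of highest signal that are present in both replicates' own thresholded lists, and up to 4 bound members with the highest signal from each list past an adjusted p of 0.05. Members of small groups that this rule does not reach, such as pqn-53, the bound panneuronal and stress genes and the genes named in the closing section, were named after their values were seen. A peak with no protein-coding 5′ end within 500 bp is given with its nearest such gene. Words of 6, 7 and 8 bases, each pooled with its reverse complement, were counted in windows reaching 50 bp to each side of the summits and in equal windows centred 300 bp to each side. The word of each length with the smallest p, corrected by Bonferroni, was picked on chromosomes I, III and V and tested once on II, IV and X with Fisher's exact test, one-sided.

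Alternatives covered the less strict list, each replicate's own list, the stronger part of the conservative list, windows of 250 and 1000 bp, other overlap rules, other backgrounds and other k-mer windows. The procedures were tested on simulated data. For summits near 5′ ends, 4 of 100 sets of 4384 randomly placed summits were called, and 20 of 20 sets with 5% of summits planted at 5′ ends. For the gene lists, 4 of 100 random sets among 19973 genes gave any call, while an 80-gene list was called in 32 of 100 sets at 2 times the chance of other genes and in 89 of 100 at 3 times. Genes in these sets were drawn independently, so the rates need not hold where neighbouring genes share a summit. A 7-mer planted in 5% of 2569 windows was recovered in 10 of 10 sets. Those windows and their background lay at random positions, not at summits and beside them. For the overlap of 500 peaks, 0 of 20 independent pairs of lists and 20 of 20 pairs sharing 5% of peaks were called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.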

Results

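Binding of MADF-6, a protein named for its MADF domain (a DNA-binding fold related to the Myb domain), was mapped across the genome of young adult Caenorhabditis elegans in 2 biological replicates. Replicate 1 gave 2803 thresholded peaks and replicate 2 gave 4519. The conservative list made from both held 4384 peaks with a median width of 320 bp and a median signal of 148.7. It is the list meant below wherever no other is named, and it covers 1185 kb. Read depth is unknown for both samples.

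The first comparison asks whether the replicates marked the same places. Of the peaks of replicate 1, 2464 of 2803 (87.9%, interval 86.6 to 89.1) overlapped a peak of replicate 2, against 2.62% after random placement (p = 0.001, permutation test, the smallest it can give). In the other direction 2427 of 4519 peaks of replicate 2 were matched (53.7%, interval 52.3 to 55.2; 1.63% at random, permutation p = 0.001). When each replicate was reduced to its 500 peaks of highest signal, so that list length could not decide the outcome, 436 (87.2%, interval 84.0 to 89.8) were shared, against 0.301% at random (permutation p = 0.001). Random placement restricted to positions of the ranked list gave 8.12%, 5.03% and 0.893% for the same comparisons. In the conservative list, 2461 peaks (56.1%) overlapped both replicates' own thresholded lists, 1192 replicate 2's alone, 137 replicate 1's alone and 594 neither.

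Genes of chromosome segregation, the eggshell and early embryos were among those beside the strongest shared peaks. Among the 25 peaks of highest signal in both replicates, whose signals ran from 2365 to 5210.8, 17 had at least 1 protein-coding 5′ end within 500 bp and together pointed to 20 genes. All 25 ranked within the first 36 peaks of replicate 1 and the first 25 of replicate 2.

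Chromosome segregation genes at these peaks included klp-18, a kinesin of the meiotic spindle (chromosome IV, 7040211 to 7043694; summit 293 bp upstream, signal 3404), which shares its peak with cogc-2 on the other strand. The others were hcp-1, which encodes a CENP-F-like kinetochore protein (chromosome V, summit 294 bp upstream, signal 3008), the shugoshin gene sgo-1 (chromosome IV, 421 bp upstream, signal 2484) and csc-1, a chromosomal passenger gene (chromosome II, 197 bp upstream, signal 2365, a peak shared with fbxc-23). The nearest 5′ ends to 2 more peaks belonged to the genes of the centromeric histone, hcp-3 (summit at 9617129 on chromosome III, 659 bp upstream, signal 3872), and of the CENP-C homologue, hcp-4 (summit at 3866626 on chromosome I, 688 bp upstream, signal 2902). The B-type cyclin gene cyb-2.2 (220 bp upstream, signal 2368) was also on the list.

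Eggshell and maternal genes were represented by cpg-1, an eggshell chondroitin proteoglycan gene (chromosome III, summit at 4489120, 239 bp upstream, signal 3578), by the chitin synthase gene chs-1 (chromosome I, 77 bp upstream, signal 2551) and by mex-1, which encodes a maternal RNA-binding protein (chromosome II, 190 bp upstream, signal 2930). A summit 522 bp upstream of the polarity gene par-3 had a signal of 2948. Other genes at these peaks were kin-35, a kinase gene (300 bp upstream, signal 4035), the glucose-6-phosphate isomerase gene gpi-1 (44 bp inside the gene, in the 5′ UTR, signal 3754), the beta-tubulin gene tbb-1 together with rib-2 (signal 2954), the histone chaperone gene nasp-2 (signal 2697) and the phosphatase gene ppm-2 (signal 2683). C01G8.1, T19H12.2, E02C12.12 and Y57G11C.5 completed the set, with signals of 3207, 3173, 2743 and 2410. The summit at Y57G11C.5 lay in an intron, 58 bp from the 5′ end of an snRNA gene. The strongest peak of all (chromosome I, 13310613 to 13311007, signal 5210.8) was intergenic, 844 bp from the 5′ end of T04D3.8, with a tRNA gene 416 bp from its summit. The remaining peaks without a gene within reach were nearest to C46C2.7 (1596 bp), slmp-1 (1627 bp), fat-1 (4117 bp) and F55D12.2 (6139 bp).

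The tagged gene itself carried a peak at its own promoter. The madf-6 gene (WBGene00016930) lies on the minus strand of chromosome I at 1011371 to 1014455, and the summit at 1014636 was 181 bp upstream of its 5′ end, with a signal of 599.9 and rank 384. Replicate 2 had this peak in its thresholded list at rank 670. Replicate 1 did not, although its ranked list held a peak with a summit at 1014635 and a signal of 260.8 there, at rank 234, with a score of only 49. Of the 9 other madf genes, madf-8 had a summit 48 bp upstream (chromosome III, 3650880, signal 207.0), found in both replicates' lists, and madf-1, madf-2, madf-3, madf-4, madf-5, madf-9, madf-10 and madf-11 had none within 500 bp. The family as a whole, with 2 of 10 genes bound, was not past the threshold (adjusted exact p = 0.394).

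**Figure D1:**
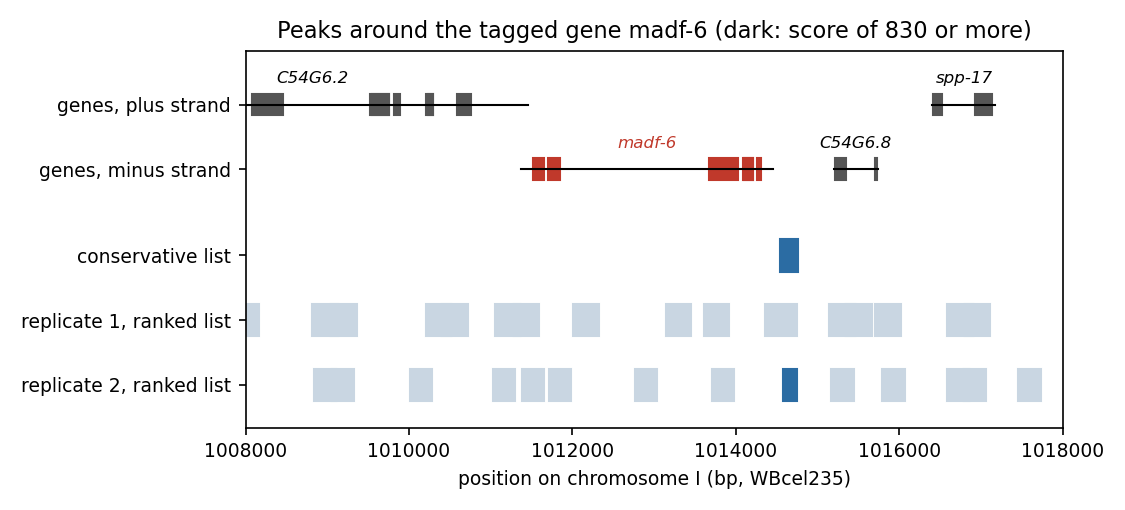
Position on chromosome I in bp (horizontal) around madf-6, with genes by strand (boxes are coding exons) above the peaks of the conservative list and of each replicate's ranked list; dark peaks have a score of 830 or more. The peak upstream of madf-6 reaches that score in the conservative list and in replicate 2, and has a score of 49 in replicate 1.

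Summits gathered at promoters. Of 4384 summits, 2172 (49.5%, interval 48.06 to 51.02) lay within 500 bp of a protein-coding 5′ end, 2.60 times the 19.02% of random placement (p = 0.002, permutation test, the smallest it can give). The share was 69.9% in the tenth of the list with the highest signal and 40.2% in the tenth with the lowest. By location, promoters held 37.5% of summits against 9.55% at random, 5′ UTRs 2.49% against 1.62%, and 3′ UTRs 4.01% against 2.75%. Coding exons (12.6% against 24.3%), introns (19.4% against 33.8%) and other intergenic sequence (20.4% against 24.4%) held fewer than at random, and each of these 6 differences had an adjusted permutation p of 0.00233. Non-coding genes held 3.60% in both, a class that leaves out summits lying beside such genes. Summits near tRNA, snRNA and snoRNA genes are described further below. The 3′ UTR excess depended on weaker peaks: among the 2192 peaks of highest signal the share was 2.01%, below the random 2.75% (permutation test, adjusted p = 0.0476), and in replicate 1's own list the excess, at 3.37%, was not past the threshold (adjusted p = 0.0583). The excess in 5′ UTRs was likewise lost among the 2192 peaks, at 2.05%.

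**Figure D2:**
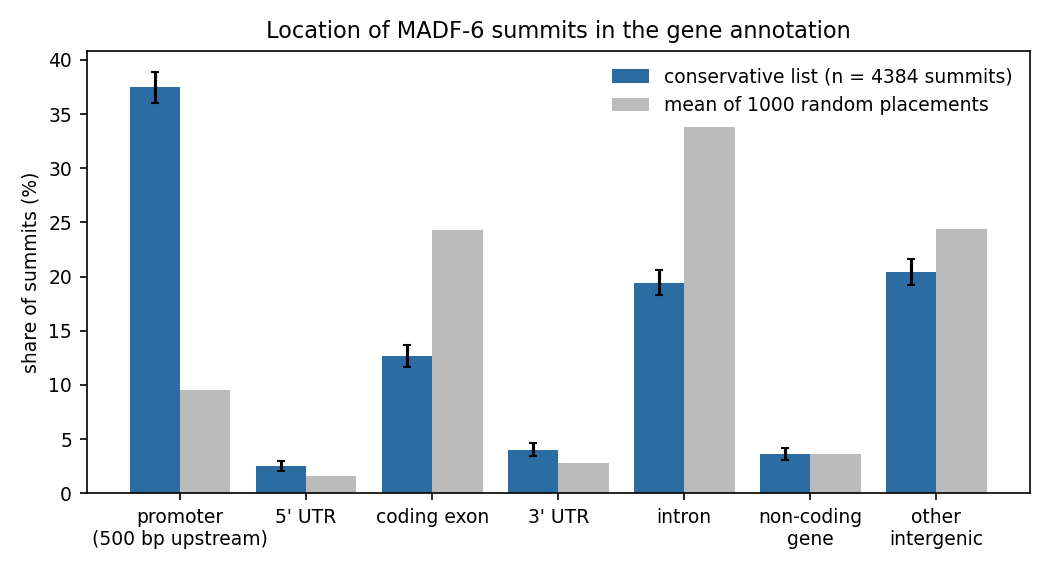
Share of summits in percent (vertical) in each location class (horizontal) for the 4384 conservative summits, with 95% Wilson intervals, beside the mean of 1000 random placements. Promoters held 37.5% of summits against 9.55% at random, while coding exons held 12.6% against 24.3%.

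Germ line and oocyte genes, ribosomal protein genes and proteasome genes were bound more often than other genes, and chemoreceptor and nuclear hormone receptor genes less often. In all, 2462 of 19973 protein-coding genes (12.3%) were bound. Of the 30 gene lists, 13 had a higher share of bound genes than the other protein-coding genes, 12 a lower share and 5 neither. Because the animals were processed whole, no list assigns a peak to a tissue. No untagged strain was analysed here, so in these lists binding cannot be told apart from unspecific recovery of strongly transcribed loci.

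Ribosomal protein genes were bound at 62 of 80 members (77.5%, odds ratio 25.1, adjusted exact p = 1.19e-39), led by rpl-3 (signal 1975), rpl-35 (1784), rpl-20 (1700) and rpl-15 (1294). Germ line and oocyte genes reached 43 of 55 (78.2%, odds ratio 25.9, adjusted exact p = 5.62e-28). They were led by mex-1 and chs-1, followed by oma-1, needed for oocyte maturation (signal 1745), and the Pumilio-family gene puf-3 (signal 1602). Among DNA replication and cell division genes 39 of 76 were bound (51.3%, odds ratio 7.60, adjusted exact p = 1.27e-15). They included mcm-2 of the replicative helicase (signal 2125), cdc-48.1, an AAA ATPase gene (1860), and pcn-1, which encodes the sliding clamp PCNA (1539). The size of these odds ratios depended on the settings. For ribosomal protein genes it was 3.55 with a window of 250 bp, where 19 of 80 were bound, 10.5 with each summit given to its nearest 5′ end, 12.7 against genes with a ranked peak and 49.0 with a window of 1000 bp. It was 19.9 in replicate 1's own list and 39.2 in replicate 2's. Over all alternatives it ran from 9.50 to 30.6 for germ line and oocyte genes and from 3.43 to 9.41 for replication and cell division genes.

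Other housekeeping groups followed. Proteasome genes were bound at 21 of 33 members (63.6%, adjusted exact p = 3.01e-11), among them pas-6 of the core particle and rpn-3 of the regulatory particle, with signals of 1100 and 854.1. The rpn-3 peak is shared with hsp-110 of the chaperone list. Splicing genes were bound at 27 of 56 (adjusted exact p = 2.11e-10), for example the SR protein genes rsp-6 and rsp-5. The name pattern behind this list also takes in rnp-8, a gene that the germ line and oocyte list holds too. Translation factors stood at 20 of 42 (adjusted exact p = 6.24e-08), including the elongation factor genes eef-2 and eef-1A.1. Chaperones reached 26 of 68 (adjusted exact p = 1.30e-07), led by the chaperonin genes cct-8 and cct-5 with signals of 1186 and 1022. Respiratory chain genes were bound at 20 of 45 (adjusted exact p = 2.22e-07), led by the cytochrome oxidase genes cox-5B and cox-5A with signals of 1660 and 960.9. Core histone genes stood at 18 of 72 (adjusted exact p = 0.00478), with his-67 and his-68 sharing a summit. Equal peak signals were also found for his-63 and his-64, his-59 and his-60, his-3 and his-4, and his-38 and his-40. The exact test counted each gene of such pairs separately, so it overstates the number of independent peaks. The call for core histone genes was lost in replicate 2's own list, where the odds ratio was 1.49. Over all alternatives their adjusted exact p ran from 1.22e-06 to 0.319. Over all alternatives the odds ratio ran from 5.02 to 28.5 for proteasome genes and from 3.09 to 9.997 for translation factors, and in replicate 2's own list it was 21.3 and 9.997. It ran from 3.09 to 8.96 for splicing genes, of which 17 were bound in replicate 1's own list, from 2.20 to 5.46 for chaperones and from 3.75 to 6.66 for respiratory chain genes.

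The remaining 4 lists with a higher share were no longer past the threshold when the background was limited to the 8886 genes with any ranked peak within 500 bp, and the second p given for each is the highest over its alternatives. With that background their odds ratios were 1.40, 2.42, 1.78 and 1.37, in the order given here. Mitochondrial ribosomal protein genes, led by mrpl-11, were bound at 22 of 66 (adjusted exact p = 1.67e-05, and 0.256 with that background). The DREAM and synMuv chromatin genes stood at 12 of 27 (adjusted exact p = 6.52e-05, then 0.0579), with lin-9, lin-53 and lin-54 of the DREAM complex at signals of 1663, 1271 and 791.3. The lin-54 peak is shared with the ribosomal protein gene rpl-12. V-ATPase and autophagy genes, led by vha-18, were bound at 15 of 46 (adjusted exact p = 4.44e-04, then 0.126), and aminoacyl-tRNA synthetase genes, led by hars-1, at 10 of 32 (adjusted exact p = 0.00561, then 0.468). The vha-18 peak is shared with pos-1 of the germ line and oocyte list.

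Chemoreceptor genes were almost never bound, at 12 of 1365 (0.879%, odds ratio 0.0585, adjusted exact p = 7.28e-61), and the odds ratio was 0.140 against genes with a ranked peak. Bound members included sri-5 (signal 400.7), srh-16 (254.7) and srw-90 (224.3), and the name pattern behind this list also takes in some genes of other families. Nuclear hormone receptors were bound at 3 of 274 (adjusted exact p = 1.92e-11), namely nhr-47, nhr-49 and nhr-102, and their odds ratio of 0.0776 was 0.0376 in replicate 1's own list, with 1 bound, 0.0488 in replicate 2's, with 2, and 0.199 with a window of 1000 bp. The nhr-47 peak is shared with dnj-19 of the chaperone list. C-type lectin and immune genes stood at 7 of 316 (adjusted exact p = 4.30e-10), led by clec-87 and clec-91, and F-box and MATH genes at 20 of 445 (adjusted exact p = 6.24e-08), led by fbxc-23, which shares its peak with csc-1.

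Genes listed by name for the body surface, neuropeptides, sperm and digestive tissues were also bound less often than other genes. The counts were 3 of 147 for hypodermis (grl-21, grl-1 and grl-26; adjusted exact p = 2.58e-05), 3 of 145 for neuropeptides and insulins (ins-37, nlp-12 and nlp-76; adjusted exact p = 3.66e-05) and 10 of 213 for cuticle collagens, led by col-38 (adjusted exact p = 3.83e-04). The col-38 peak is shared with the ribosomal protein gene rpl-5. In replicate 1's own list 1 hypodermis gene and 1 neuropeptide or insulin gene were bound, and in replicate 2's 4 and 2. Over all alternatives the odds ratio ran from 0.0709 to 0.191 for hypodermis, from 0.0719 to 0.309 for neuropeptides and insulins and from 0.106 to 0.405 for collagens. Detoxification genes stood at 14 of 256 (adjusted exact p = 5.64e-04, and 0.0770 against genes with a ranked peak), led by the cytochrome P450 genes cyp-31A3 and cyp-31A2, with 8 bound in replicate 1's own list and 18 in replicate 2's. Sperm genes were bound at 4 of 102 (adjusted exact p = 0.00825), with spe-39, a gene of vesicle traffic, at a signal of 1099, spe-5 at 167.6 and spe-15 at 160.8. The spe-39 peak is shared with spn-4 of the germ line and oocyte list. Pharynx genes stood at 5 of 106 (adjusted exact p = 0.0215), at pqn-21, pqn-51, pqn-27, pqn-80 and pqn-53, whose name stands for proteins rich in glutamine and asparagine and not for expression in the pharynx. Intestine genes stood at 6 of 114 (adjusted exact p = 0.0262) and body wall muscle genes at 1 of 47 (mlc-3; adjusted exact p = 0.0307). The summit at the vitellogenin gene vit-2 lay inside a coding exon with a signal of 92.0, while the median of the list was 148.7. The calls for sperm, pharynx, intestine and muscle genes each ended when the window was narrowed to 250 bp. Their odds ratios there were 0.341, 0.441, 0.626 and 0.245, in that order, against 0.289, 0.351, 0.394 and 0.154 with 500 bp. In replicate 1's own list the odds ratio rose from 0.289 to 0.536 for sperm genes and from 0.351 to 0.736 for pharynx genes, and neither was past the threshold. The counts for intestine genes were 1 in replicate 1's own list and 4 in replicate 2's (odds ratios 0.0917 and 0.244, against 0.394), and no muscle gene was bound in either. Homeodomain genes (6 of 96, adjusted exact p = 0.0977), members of the panneuronal list (4 of 49, namely tbb-1, unc-11, tba-1 and ehs-1; 0.551), stress regulators (4 of 34, namely daf-2, crh-1, xbp-1 and atf-7; 1) and signalling genes (6 of 52, 1) were not past the threshold, which homeodomain genes crossed, in the lower direction, with the less strict peak list and without peaks near tRNA, snRNA or snoRNA genes. The panneuronal list was drawn up by gene name and takes in the tubulin genes tbb-1 and tba-1, so its share need not describe neuronal genes.

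**Figure D3:**
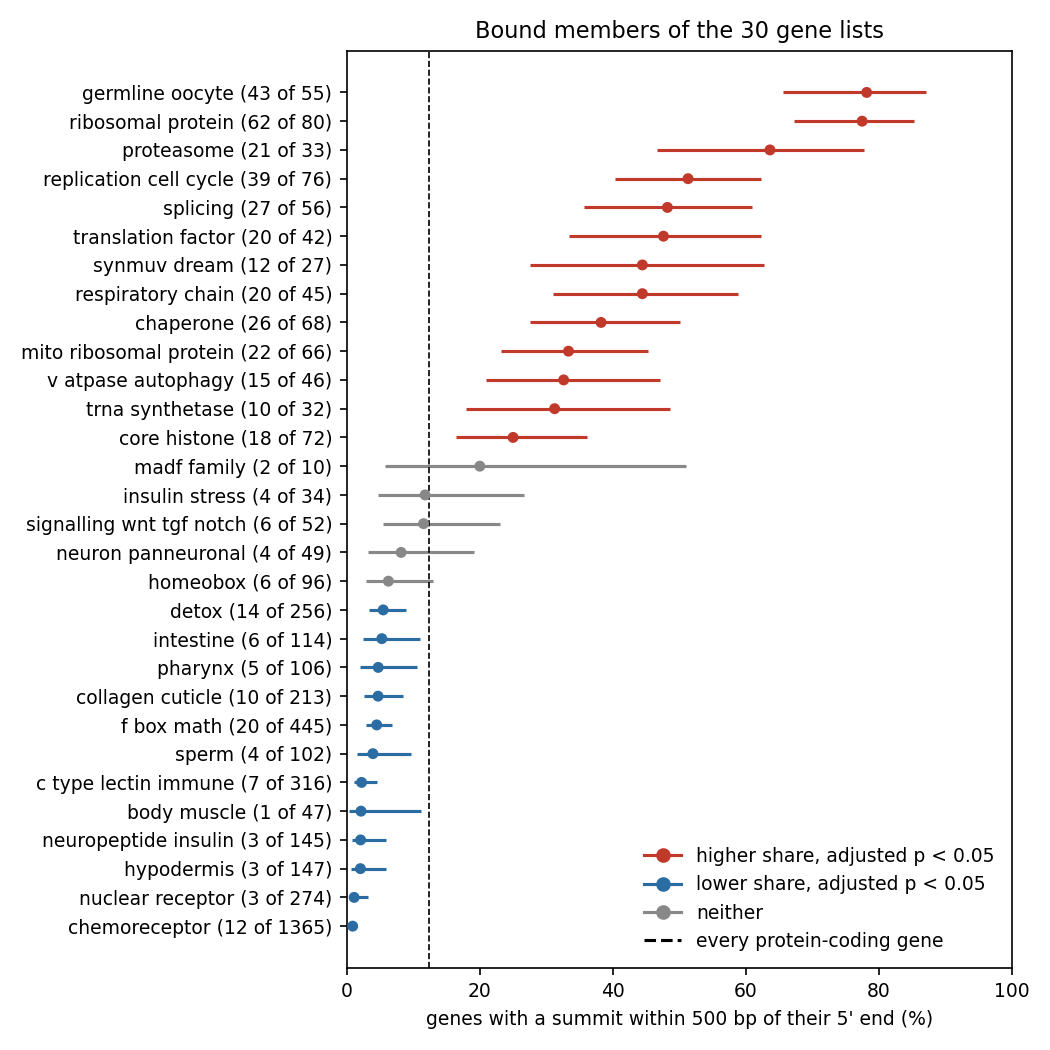
Share of bound genes in percent (horizontal) in each of the 30 gene lists (vertical), with 95% Wilson intervals; colours mark an adjusted p below 0.05 in either direction, and the dashed line is the 12.3% of protein-coding genes bound. Germ line and ribosomal protein genes lie at 78.2% and 77.5%, chemoreceptors at 0.879%.

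The X chromosome carried few peaks. Only 51 of 2731 X-linked protein-coding genes (1.87%) were bound, against 2411 of 17242 autosomal genes (13.98%), an odds ratio of 0.117 (Fisher's exact test, p = 2.92e-100). Summit density was 11.3 per Mb on X and 50.7 per Mb on the autosomes, which ranged from 34.7 on chromosome V to 68.5 on chromosome III. The ranked list was also sparser on X, with 346 against 699 peaks per Mb. Among genes that had a ranked peak within 500 bp, 7.96% on X and 29.2% on the autosomes were bound (odds ratio 0.209, exact p = 7.28e-38). Over all protein-coding genes the odds ratio was 0.0730 in replicate 1's own list and 0.0554 with the 2192 peaks of highest signal. With each autosome divided into 3 equal parts, density was 46.6 summits per Mb in the outer parts and 58.8 in the middle part, a ratio of 0.793 (p = 0.002, permutation test). Genes are not independent replicates, so these p-values describe the distribution in these lists.

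**Figure D4:**
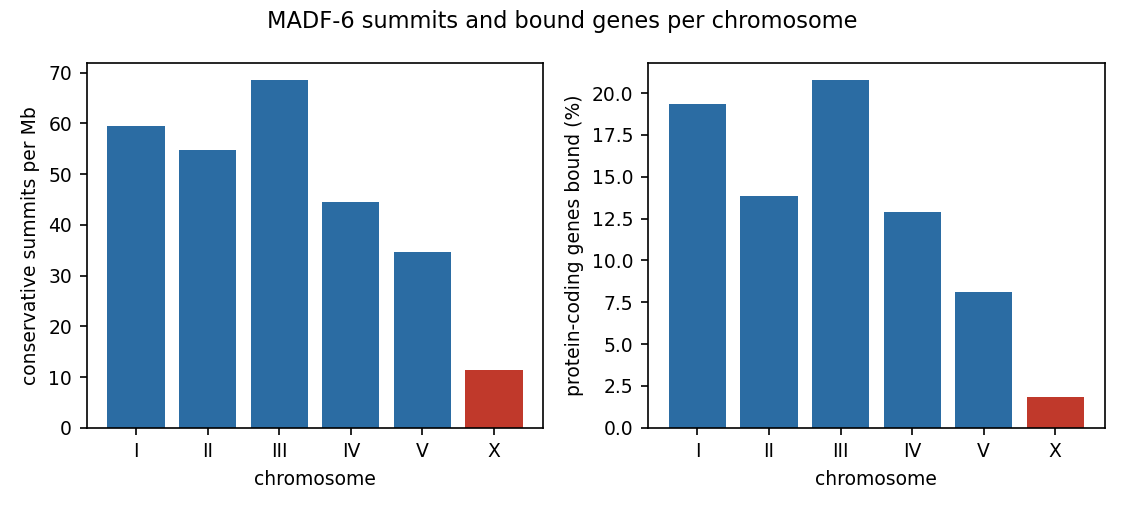
Conservative summits per Mb (left) and percent of protein-coding genes bound (right) for each chromosome. X stands at 11.3 summits per Mb and 1.87% of genes, below each autosome.

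Short GC-rich words marked the summits. On the held-out chromosomes II, IV and X, AAAGGCGC was present within 50 bp of 149 of 1815 summits (8.21%, interval 7.03 to 9.56) and in 22 of 3630 windows beside them (0.606%), a 13.5-fold difference (Fisher's exact test, p = 9.08e-50). The leading 7-mer, AAGGCGC, is contained in it and was 9.74-fold more frequent (10.5% against 1.07%, exact p = 2.10e-56). The leading 6-mer, CGCGCC, was found at 9.70% of summits and 1.32% of flanks (7.33-fold, exact p = 1.16e-45). These folds depended on the windows and the background. They were 4.68, 4.13 and 3.79 for the words of 8, 7 and 6 bases with windows reaching 100 bp to each side, and at most 24.8, 16.5 and 11.4 under the other alternatives run. After windows with the leading 7-mer were set aside in turn, a step chosen after that result was seen, CGCGCGC, GTACGCA, GAGACGC and CGCGCCA emerged, with 13.1-fold, 6.47-fold, 5.33-fold and 9-fold differences on the held-out chromosomes. At least 1 of these 5 words of 7 bases was present at 24.4% of the held-out summits and in 3.06% of flanks, so most summits held none of them.

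**Figure D5:**
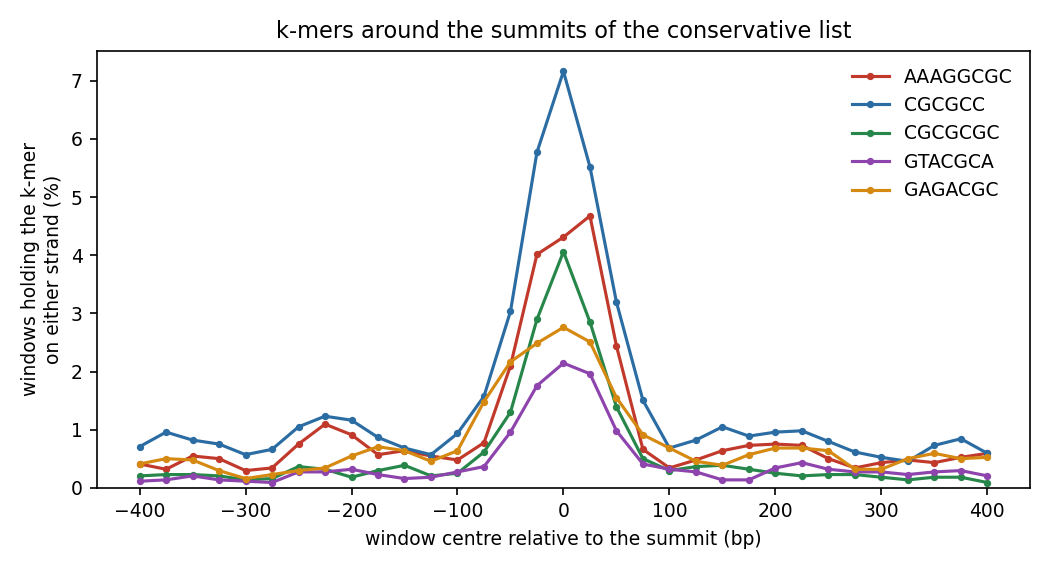
Percent of windows reaching 25 bp to each side that hold each word on either strand (vertical) by the distance in bp of the window centre from the summit (horizontal), for all 4384 conservative summits. Each word peaks within 50 bp of the summit.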

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

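The explanations below were weighed once the patterns had been seen, and the test of list length was chosen only after its result was known. The samples form a single group, so no biological explanation was tested by a contrast of samples.

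The 5′ ends of transfer RNA genes were not counted in the comparisons of bound genes, which use protein-coding genes, and many had a summit nearby. Of 612 nuclear tRNA genes, 280 (45.8%) had a conservative summit within 500 bp of their 5′ end, against 3.31% at random, and 44.96% of 129 snRNA genes and 37.6% of 346 snoRNA genes did too. In the replicates' own lists the share for tRNA genes was 27.3% in replicate 1 and 46.7% in replicate 2. Reads shared between gene copies stay open as a cause. Of the 140 tRNA genes whose exact sequence occurs once in the genome 34.3% had a summit, above the 8.57% that was the highest of the random placements. The share was 49.2% for the 472 tRNA genes of repeated sequence. These shares cannot decide the question, because copies that differ slightly counted as single. A summit at a neighbouring tRNA gene within 500 bp counted too. Promoters of neighbouring protein-coding genes did not account for the summits at tRNA genes, because tRNA genes more than 1000 bp from any protein-coding 5′ end had a summit in 43.6% of cases, against at most 6.09% at random. Unspecific recovery of strongly transcribed loci cannot be told apart from binding: 11.0% of the 246 summits near tRNA genes held at least 1 of the 5 summit 7-mers, more than the 3.66% beside them but less than the 28.2% of summits away from small RNA genes, and no untagged sample was analysed here.

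Replicate 1's own thresholded list held 12 peaks on the mitochondrial genome, where replicate 2 had 0 in either of its lists. Each list that combines the replicates also held 0 there, including the ranked lists of 63808 and 65766 peaks. Why the combined lists lack the peaks of replicate 1 was not tested. The comparisons of locations and genes do not use that genome. The signals of the 12 peaks ran from 208.9 to 2057. The last was the highest of replicate 1's thresholded list (4604 to 4860 of the mitochondrial genome), whose nuclear median was 71.7. A longer list in replicate 1 is not the cause, since its ranked list held 57453 peaks and replicate 2's held 65847. Uneven recovery of mitochondrial DNA between library and control remains a possible explanation that the values at hand cannot decide. The peaks covered 22.6% of the 13794 bp, a share set largely by the number and width of the peaks in question. Of the 12 peaks, 0 held any of the 5 summit 7-mers. How often these GC-rich words occur in the rest of the mitochondrial genome was not counted.

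The low density on X was weighed in the same way. Gene content as the lists describe it was not the whole cause, since within the lists with a higher share of bound genes 4 of 34 X-linked members were bound (his-38, his-40, meg-1 and snrp-40.1) and 330 of 662 autosomal ones (odds ratio 0.134, Fisher's exact p = 9.92e-06). The X-linked members include paralogs such as rpl-11.2, rpl-25.1 and eef-1A.2, whose expression was not analysed here, so a difference in where the genes are used stays open. The odds ratio for tRNA genes, 0.417 (interval 0.296 to 0.586), lay above that for protein-coding genes, 0.117 (interval 0.0866 to 0.155). This cannot decide whether a lower recovery shared by all X chromatin was the whole cause. A loss of signal before thresholding need not give equal odds ratios in classes that differ in their share with a summit. On autosomes that share was 55.4% for tRNA genes and 13.98% for protein-coding genes. A lower recovery, in whole or in part, stays open. The tRNA genes on X did have fewer summits than those on autosomes (34.1% against 55.4%). The interval of the odds ratio for snoRNA genes, 0.146 (0.0281 to 0.488), overlapped both of the others.

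In the ranked list behind the conservative one, 57 peaks reached the score of the conservative list and are not in it, so no bound gene rests on them. The strongest of them lies on X at 15810946 to 15811167 with a signal of 2072.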

How the results depend on the processing

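The overlap of replicates, the share of summits near 5′ ends, the contrast of X with autosomes, that of outer with middle chromosome parts and the leading k-mers kept their direction and their side of the threshold under the alternatives run for each. The number of locations past the threshold was 5 or 6, that of gene lists with a higher share 9 to 13 and that of lists with a lower share 8 to 13, so single lists did change. The number of bound genes fell from 2462 to 1579 when only the 2192 peaks of highest signal were used and to 1625 with a window of 250 bp, as fewer peaks or a narrower window must give. The 3′ UTR share reversed to 2.01% among the peaks of highest signal, below its random level; the cause was not tested. Among single locations and gene lists, 31 values lost their call and 2 gained it. Leaving out a replicate, which means using the other's own list, gave 49.3% to 52.7% of summits near a protein-coding 5′ end, 1748 to 2581 bound genes and an odds ratio for X of 0.0730 to 0.113. Requiring a score of at least 830 removed no peak and tests nothing, and keeping only peaks at the cap of 1000 left 3614. Alternatives added after seeing the data were that cap, merging overlapping peaks (50.1% near 5′ ends), leaving out peaks near tRNA, snRNA or snoRNA genes (52.7%) and giving each summit to its nearest 5′ end. No paired analysis was possible because there is 1 group. Depth is unknown, so a gene without a peak may still be bound below what these libraries could detect.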

Other observations

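Everything in this part was chosen after the data had been seen: the gene lists were drawn up once the strongest peaks were known, though their tests were written down before they were run.

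Kinetochore and chromosome segregation genes may be bound as a group, beyond the strongest peaks. Leaving out members at the 25 strongest peaks and members of the lists fixed earlier, 32 of 45 such genes were bound (71.1%), against 12.1% of other protein-coding genes (odds ratio 17.8, Fisher's exact p = 8.50e-20). The bound members included cpar-1, a second centromeric histone gene (signal 1540), the meiotic spindle genes mei-2 (1786), klp-15 (1234) and klp-16 (1505), the spindle-positioning gene lin-5 (1617), the separase gene sep-1 (212.6), the condensin gene smc-4 (887.9) and the centriole genes sas-5 (622.7) and zyg-1 (216.1). Those without a summit within 500 bp included hcp-2, him-10, mis-12 and klp-7. Of the eggshell genes, 8 of 13 were bound outside the strongest peaks (61.5%, odds ratio 11.4, exact p = 3.75e-05), among them cpg-2 (signal 2132), perm-1 (1868), egg-4 (1351) and egg-6 (857.6), while perm-2, perm-4, perm-5, mbk-2 and chs-2 were not.

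The words at the summits were also counted by gene group, and some groups and words, picked after the counts were seen, are given here. The word AAGGCGC was present at 33.3% of 45 summits beside germ line and oocyte genes, 18.8% of 69 beside ribosomal protein genes and 4 of 40 beside replication and cell division genes. The last group held CGCGCGC at 8 summits and GTACGCA at 7 of the 40, while 1 and 0 of the 45 germ line and oocyte summits did. These differences between groups were not tested.

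Stronger and weaker peaks lay in different places. Coding exons held 4.11% of the summits in the stronger part of the list, split at its middle, and 21.2% in the weaker part (odds ratio 6.27, adjusted exact p = 9.10e-69), while promoters fell from 50.1% to 24.8%. In the whole list 98 peaks had a signal below 20, and 97 of them overlapped a stronger peak of the same list. Among other kinds of gene, miRNA genes (8.81% against 4.01% at random, permutation p = 0.004) and lincRNA genes (8.76% against 4.23%, permutation p = 0.006) had a summit within 500 bp more often than at random. By contrast, piRNA genes had a summit within 500 bp in 107 of 15363 cases (0.696%, against 4.32% at random, permutation p = 0.002) and pseudogenes in 3.81% (4.20% at random, permutation p = 0.372). Random placement spread summits evenly along each chromosome, which the real summits were not. These contrasts may therefore also reflect the regions in which each kind of gene lies.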
